A study of Arabidopsis thaliana with 14 samples.

How the data were processed

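Transcript levels of Arabidopsis thaliana were measured on 14 Affymetrix ATH1 arrays, which carry 1 label each (biotin). Per the labels, 4 arrays were controls on Col-0 plants at 12, 24, 48 and 72 h, and 2 arrays were made for each of 5 attackers at 2 time points. The samples were grouped by the attacker and the hour in their titles, and every title names a single replicate, so no group holds replicates. The fungus Alternaria brassicicola was put on the mutant pad3-1, per the labels, while every control array came from Col-0. No control with an empty inoculum or an insect-free cage was analysed here.

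The deposited values are an intensity per probe set on a linear scale, the signal made with MAS5 per the submitters' processing notes. The version, the filters and the detection calls of that step are not given in the sources used here. From the values, the deposited signal had been scaled on each array so that its trimmed mean, leaving out 2 percent at each end, was 100. This scaling makes arrays comparable only as far as most transcripts stay level. It was kept as deposited, and the median change over all probe sets kept was -0.16 on the log2 scale for P. syringae, 0.06 for M. persicae and between -0.02 and 0.01 for the other attackers. After quantile normalization it was -0.12 for P. syringae.

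The arrays carry 22810 probe sets, of which 64 are control probe sets and were left out of the tests. The platform annotation used here lists 1 gene for 13513 probe sets, several for 503 and none for 8794. A probe set without a listed gene is unnamed here and is given by its probe set identifier, and none was named from a probe set with several genes. Of the probe sets with 1 gene, 13436 matched a locus of the reference gene table, and 1580 carry a symbol other than the locus. Signals under 25 were set to 25 before log2 was taken, because MAS5 signals near the background are unstable. A ratio in which the lower signal was set to this floor is a lower bound, and a fitted change of such a gene depends on the floor. A probe set was kept if its signal was at least 50 on at least 2 arrays, which left 12344, of which 6502 have 1 gene.

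With 1 array per attacker and time point, the change that an attacker shares between its 2 time points was tested in an additive linear model with attacker and time point as factors over all 14 arrays, with 5 residual degrees of freedom. limma (version 3.58.1, in R 4.3.3) was used with moderated variances that follow the mean signal (median prior degrees of freedom 3.8), two-sided, and with Benjamini-Hochberg adjustment over all probe sets kept at 0.05. The residual spread holds array noise together with any real change of the response over time, so an effect seen at 1 time point only is not called. Nothing in the labels says which arrays come from separate sets of plants, so p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision. A log2 change is given with the standard error of the fit. The time effects of the fit come from all 14 arrays, so a fitted change can lie outside the attacker's 2 ratios to the control arrays of the same hour. For AT4G12490 with P. syringae it was 5.64, against ratios of 4.83 and 5.22. Beside this test, probe sets at least 2-fold from the control array of the same hour in the same direction at both time points were counted, which involves no test. Their number without any effect was taken from 100 simulations of 14 unchanged arrays with the residual spread of each probe set. These simulations leave out differences between control arrays of different hours, so the number between unattacked arrays can be higher. With the 24 h control as reference, 617 probe sets were at least 2-fold higher and 624 lower on both later control arrays.

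Differences between attackers were tested as contrasts in the same model. Overlaps between attackers were set beside the number for independent lists and beside the simulated number, since attackers share control arrays. Gene lists were tested with camera of limma at a preset correlation of 0.01 over 40 lists and 5 attackers, with Benjamini-Hochberg adjustment over the 200 tests. The test was repeated with an estimated correlation, and fry of limma gives a p-value for a movement of the members in 1 direction. Of the 24 lists fixed before the data were examined, which hold 463 genes, 64 genes had a probe set listed for them alone and 55 were kept. The 8 fixed lists with at least 3 kept members were tested, together with 32 lists by locus or by symbol family that were added once the annotation had been read and before signals were looked at. Of the 200 tests, 19 passed with the preset correlation, 0 with the estimated correlation, and 49 had an unadjusted fry p under 0.05. Each list's median ratio on an array was also placed among 10000 random lists of the same size and matched mean signal.

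The genes named for an attacker are, among probe sets with 1 gene that passed the test and were at least 2-fold at both times, the 12 with the largest increase and the 8 with the largest decrease. Where fewer than 5 passed in a direction, probe sets at least 2-fold at both times were added up to 5, ranked by the smaller of the 2 ratios, and these are said not to have passed. Further names are the members with the largest changes of each list described, the 5 most different genes each way between attackers, probe sets called in 4 or more attackers and 5 defence marker genes, of which only PDF1.2 had a probe set listed for it. The few probe sets called for A. brassicicola and for P. rapae without a listed gene, and the genes GI and COR15A in the account of the control arrays, were named after their values had been seen.

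The test was checked on simulated data in which 200 of 12344 probe sets were changed. For a log2 change of 1 it recovered 12 percent for P. syringae, 22 for A. brassicicola, 13 for P. rapae, 18 for F. occidentalis and 16 for M. persicae. For a log2 change of 3 it recovered 99, 100, 100, 96 and 98 percent in the same order, with 8, 7, 9, 3 and 7 false calls. These simulated arrays held independent noise around a single mean per probe set. They left out time effects, the floor, correlation between probe sets and differences between control arrays. The numbers therefore need not hold for the real arrays, where the share of changed probe sets may also differ.

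The alternatives tried were floors of 10 and 50, log2 of the signal plus 16 without a floor, no filter, a minimum of 100, quantile normalization, time as 12 h against later hours, variances without a trend, the Col-0 arrays alone, each attacker with its own control arrays alone, each array left out in turn, a pooled control, and 3-fold at both times. Further alternatives were chosen after seeing the data: the F. occidentalis arrays taken as 12 and 24 h or left out, the 24 h control array as the reference for every later array, and the fit without the 48 and 72 h control arrays, also with time as 12 h against later hours. The fits on an attacker's own arrays and control arrays alone have fewer residual degrees of freedom than the main fit. Their spread rests more on the moderated variances, so their counts are not comparable with those of the main fit. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.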

Results

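The series follows the transcript profile of Arabidopsis thaliana plants under attackers with different ways of feeding or infecting. Each of 14 ATH1 arrays holds 1 condition at 1 time point. 4 control arrays held Col-0 plants at 12, 24, 48 and 72 h. Col-0 plants were inoculated with the bacterium Pseudomonas syringae pv. tomato DC3000 carrying the avirulence gene avrRpt2 (12 and 24 h), or infested with the leaf-chewing caterpillar Pieris rapae (12 and 24 h), the cell-feeding thrips Frankliniella occidentalis (24 and 48 h) or the phloem-feeding aphid Myzus persicae (48 and 72 h). The fungus Alternaria brassicicola was put on pad3-1 plants, which lack the camalexin synthesis gene PAD3 (24 and 48 h). Between 9761 and 10492 of the 22810 probe sets reached a signal of 50 on an array. There are no replicates, and the tests concern the change that the 2 arrays of an attacker share. Their p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

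Among the control arrays, GI and COR15A were lower at 12 h than at the later hours. The signal of GI (AT1G22770), a clock gene, was 12.1 at 12 h and 360.3, 127.2 and 186.4 at 24, 48 and 72 h. The signal of COR15A (AT2G42540), a cold-regulated gene, was 36.6 at 12 h and 969.3, 657.2 and 1310.4 at the later hours. PDF1.2 and COR27 were lower at 48 and 72 h than at 24 h. The defensin gene PDF1.2 (AT5G44420), a marker of jasmonate and ethylene signalling, had signals of 352.4, 375.3, 34.7 and 30.3 from 12 to 72 h, and the cold-regulated gene COR27 (AT5G42900) had signals of 191.5, 169.3, 1.1 and 0.9. These control values had no replicate check, and GI and COR15A were chosen after their values were seen. Between control arrays, 1456 probe sets differed at least 2-fold from 24 to 48 h, 2396 from 24 to 72 h, 688 from 48 to 72 h and 1239 from 12 to 24 h. Against the 24 h control, 617 probe sets were at least 2-fold higher and 624 lower on both the 48 and 72 h control arrays. Against the 72 h control, 271 were higher and 301 lower on both the 24 and 48 h control arrays. Against the 48 h control, 29 were higher and 12 lower on both the 24 and 72 h control arrays. The log2 ratio of the 3' to the 5' actin probe sets, a sign of RNA quality, was 2.2 on the 72 h control array, 1.87 on the P. syringae 24 h array, 1.5 on the F. occidentalis 24 h array and 1.4 on the 48 h control array, and between 0.47 and 1.13 on the other arrays. For ubiquitin this ratio was 0.98 on the 72 h control array, 1.04 on the P. syringae 24 h array, 1.21 on the F. occidentalis 24 h array and 1.00 on the 48 h control array, and between 0.58 and 1.09 on the others. For GAPDH it was -0.04, 0.22, 0.05 and -0.03 on these 4 arrays and between -0.47 and 0.12 on the others.

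The 60 probe sets that differed at least 4-fold in the same direction between the 12 h control and every later control gave each array a position between 0 (12 h control) and 1 (mean of the later controls). The P. syringae and P. rapae 12 h arrays had median positions of 0.27 and 0.13. The arrays of P. syringae, A. brassicicola and P. rapae at 24 h and of A. brassicicola and F. occidentalis at 48 h lay between 0.87 and 0.96. The F. occidentalis 24 h array lay at 0.16, and GI and COR15A had signals of 12.9 and 50.7 on it. The M. persicae arrays lay at 0.65 (48 h) and 0.46 (72 h).

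**Figure D1:**
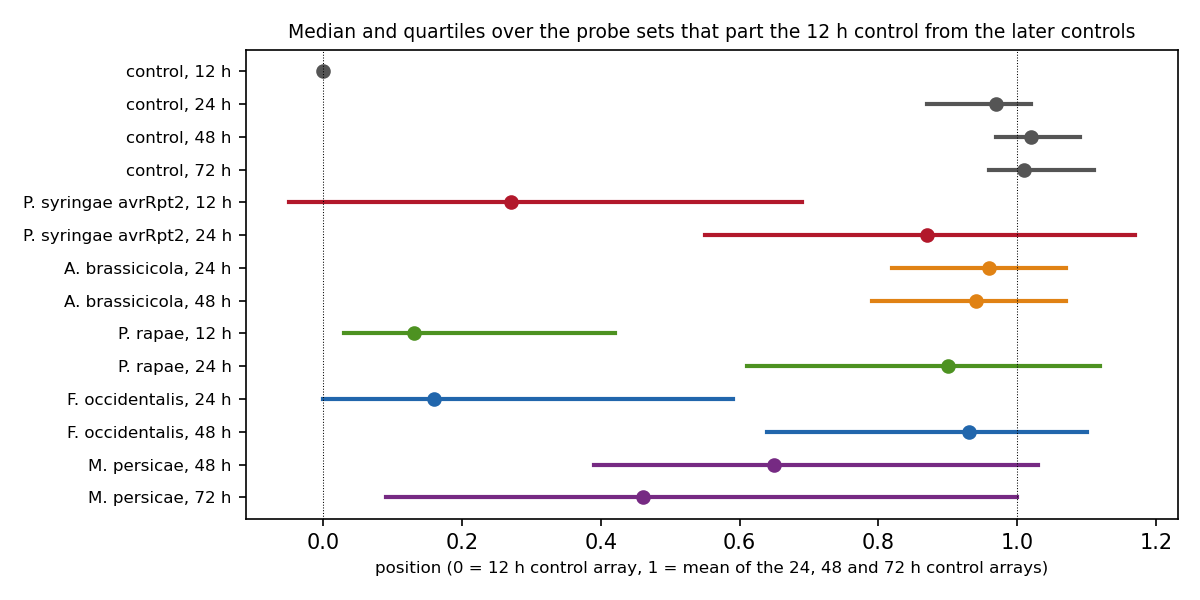
Median position (points) and quartiles (lines) of each array over the 60 probe sets that separate the 12 h control array (0) from the later control arrays (1); the x axis has no unit and colours mark the attacker. The F. occidentalis array of 24 h sits at 0.16, near the P. rapae (0.13) and P. syringae (0.27) arrays of 12 h.

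Among probe sets with 1 listed gene, P. syringae DC3000 with avrRpt2, a strain recognised by Col-0 plants, gave its largest increases at JRG21 and at a chitinase gene. JRG21 (AT3G55970) and AT2G38240, which encode oxygenases that inactivate jasmonate, rose by log2 6.45 ± 0.73 (SE, adjusted p = 7e-04) and 6.00 ± 0.66 (adjusted p = 0.000605) over the 2 time points. The chitinase gene AT2G43570 rose by 6.42 ± 0.47, the salicylate-responsive glutaredoxin gene GRX480 (AT1G28480) by 4.88 ± 0.39, the methionine sulfoxide reductase gene MSRB9 (AT4G21850) by 5.51 ± 0.52 and the osmotin gene OSM34 (AT4G11650) by 4.66 ± 1.14, a call lost without the 24 h array (adjusted p = 0.191). AT3G18250 (6.08), the lipid-transfer family gene AT4G12490 (5.64), the berberine bridge-type oxidoreductase gene AT1G26390 (5.42), AT1G68620 (5.37), AT1G05340 (4.65) and AT5G03610 (4.65) complete the 12 largest increases among probe sets with 1 listed gene. Probe sets without a listed gene rose as well, such as 256933_at (6.29), 261763_at (5.82) and 267567_at (5.37). The largest decreases among probe sets with 1 listed gene were those of AT1G73600 (-3.18 ± 0.56), AT1G30250 (-2.97), AT5G55620 (-2.83), DRT100 (AT3G12610, -2.82 ± 0.24), AT1G78995 (-2.73), AT2G29290 (-2.70), AT5G03120 (-2.57) and AT3G15570 (-2.49). For 8 of the 12 increases at least 1 of the 2 control signals was under the floor of 25, so the ratio there is a lower bound. PDF1.2 had signals of 204.1 at 12 h and 2897.6 at 24 h, against 352.4 and 375.3.

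Of 8 kept genes for chitinases, glucanases and related proteins, all 8 rose at both times, by a median of log2 3.2, among them AT3G47540 (4.32 ± 0.45), AT4G16260 (3.84 ± 0.58), a glucanase gene, and AT4G01700 (2.56 ± 0.30). The list passed against other genes (adjusted p = 4.54e-06, and adjusted p = 0.716 with an estimated correlation). Of 4 kept genes of salicylate signalling, 2 rose, or 3 when adjusted over the list alone: GRX480 and SARD4 (AT5G52810, 1.94 ± 0.35) passed over all genes, while WRKY53 had 2.46 ± 0.98 (adjusted p = 0.0892). The list had adjusted p = 0.028, and adjusted p = 0.716 with an estimated correlation. Of 5 genes of early immune signalling, 4 rose over all genes and 4 when adjusted over the list alone, with PUB24 at 2.24 ± 0.38, BIK1, a receptor-associated kinase gene, at 2.09 ± 0.48 and ZAT10 at 1.59 ± 0.46 (list adjusted p = 0.0272, and adjusted p = 0.716 with an estimated correlation). The calls of the salicylate and early immune lists were also lost with a signal minimum of 100. Of 3 genes for protein folding in the endoplasmic reticulum, 2 rose (3 when adjusted over the list alone), the calreticulin gene CRT1B by 0.99 ± 0.20 and BZIP60 by 1.35 ± 0.41, and the list did not pass (adjusted p = 0.0894, and adjusted p = 0.716 with an estimated correlation). Of 10 photosynthesis genes, 2 fell over all genes and 2 when adjusted over the list alone, the Calvin cycle genes PRK by -1.43 ± 0.23 and SBPASE by -1.66 ± 0.26, and the list's median was -0.89 (adjusted p = 0.0549, and adjusted p = 0.794 with an estimated correlation). Of 5 cell wall loosening genes, 3 fell (3 when adjusted over the list alone), led by the expansin gene EXPA8 with -2.32 ± 0.46, and the list did not pass (adjusted p = 0.244). Among lists with fewer than 3 kept genes, WRKY6 (3.93 ± 0.28), the lignin gene CCR2 (2.95 ± 0.23), JMT (2.52 ± 0.25), whose product methylates jasmonate, and IGPS of tryptophan synthesis (2.28 ± 0.29) rose, as did ATG8A (1.44 ± 0.37) and OPCL1 (1.08 ± 0.33), and the glucosinolate synthesis gene UGT74C1 fell (-1.65 ± 0.43, adjusted p = 0.021). In these small lists THI2.1 (1.24 ± 0.43) passed when adjusted over the list alone and not over all genes. UGT74B1 (0.76 ± 0.33), the only kept gene of its list, had an unadjusted p of 0.0493 in limma and did not pass over all genes (adjusted p = 0.118). Of the other tested lists, auxin response had 1 of 3 genes higher (GH3.3, 3.36 ± 0.95, and 1 when adjusted over the list alone), while 0 of 4 abscisic acid, drought and cold genes and 0 of 3 flavonoid genes passed in limma over all genes or when adjusted over the list alone (list adjusted p = 0.429, 0.887 and 0.382).

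In all, 1582 probe sets were higher and 2070 lower with P. syringae in limma, and 5165 had an unadjusted p under 0.05. At least 2-fold at both times, 990 were higher and 892 lower, against a simulated mean of 27.6 and 28.0 without an effect, and 1737 met both criteria. Without the 12 h control array 784 were higher and 612 lower in limma, without the P. syringae 12 h array 787 and 659, and without the P. syringae 24 h array 1162 were lower. With the P. syringae arrays and their own 2 control arrays alone 1095 were lower. Of the 20 named genes, 14 kept their call whichever array was left out, and OSM34, AT1G73600, AT5G55620, AT5G03120, AT1G78995 and AT3G15570 did not.

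**Figure D2:**
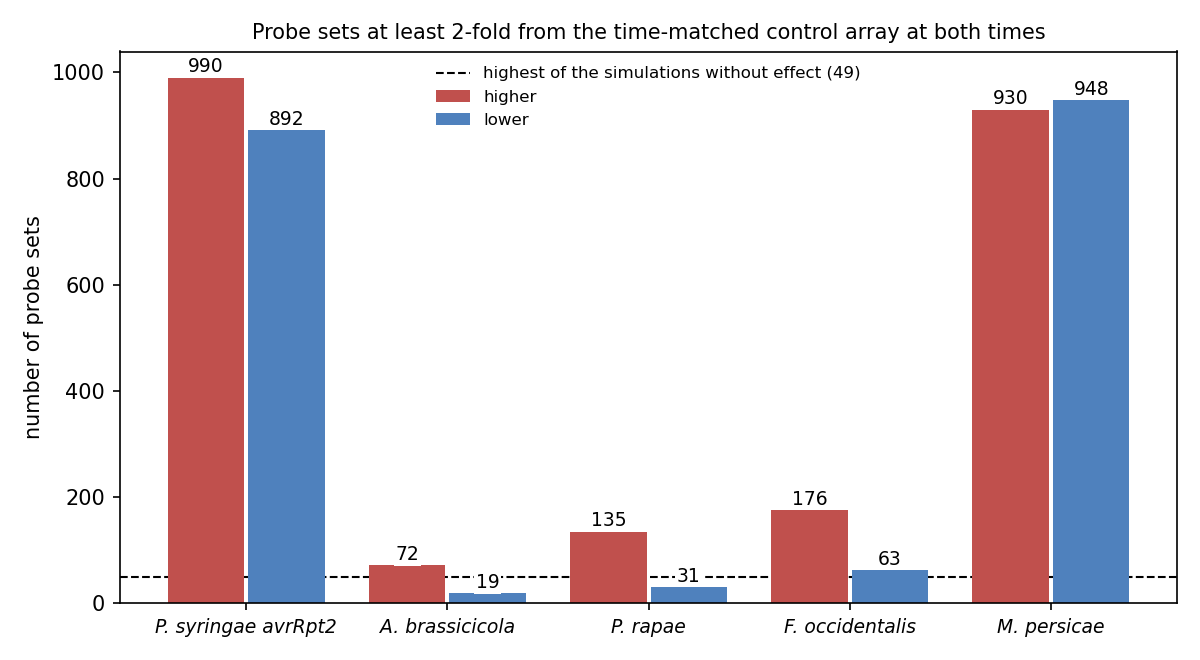
Number of probe sets (y axis) at least 2-fold higher (red) or lower (blue) than the control array of the same hour at both time points of each attacker (x axis); the dashed line marks 49, the highest number in 100 simulations without an effect. P. syringae (990 and 892) and M. persicae (930 and 948) stand far above the other attackers. The simulations leave out differences between control arrays of different hours, among which up to 617 were higher and 624 lower.

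A. brassicicola on pad3-1 plants was compared with Col-0 controls, so fungus and genotype cannot be separated here. AT1G26380, a berberine bridge-type oxidoreductase gene, rose by log2 2.96 ± 0.35 (adjusted p = 0.0325), with signals of 187.3 and 174.5 against 5.5 and 4.7 in the controls, both under the floor. Of the 6 probe sets that rose, the other 5 have no gene listed and were named after their values were seen: 251847_at (1.98), 252265_at (4.32), 256933_at (3.83), 261763_at (2.44) and 267567_at (3.81), and all 6 also rose with P. syringae. PDF1.2 had signals of 1879.2 and 4394.6 against 375.3 and 34.7, log2 ratios of 2.32 and 6.99, and did not pass over all genes (3.79 ± 1.24, adjusted p = 0.577). It and PDF1.2b (3.6 ± 1.24) passed in limma when adjusted over the list alone (adjusted p = 0.0179 for both). PDF1.2b had similar signals (1603.6 and 3782), so the 2 probe sets may not be separate measurements, with this or any other attacker. IGPS (1.1 ± 0.28), the only kept gene of its list, had an unadjusted p of 0.00399 in limma and did not pass over all genes (adjusted p = 0.39). AT4G16260 (4.00 ± 0.56, adjusted p = 0.0958), AT2G43570 (2.96 ± 0.46, adjusted p = 0.126) and AT2G41730 (2.11) were at least 2-fold higher at both times and did not pass. Among probe sets with 1 listed gene, the leading values below the controls were those of AT1G80130 (-1.71), AT5G18600 (-1.63), AT3G55920 (-1.49), AT2G45600 (-1.48) and AT4G30650 (-1.42), none of which passed.

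The chitinase and glucanase genes had a median of 0.87 with A. brassicicola (0 of 8 passed, list adjusted p = 0.00054, and adjusted p = 0.716 with an estimated correlation). The heat shock protein genes had a median of 0.68, with AT2G29500 at 1.90 and AT5G51440 at 1.52 (0 of 8 passed, list adjusted p = 0.00533), the mitochondrially encoded genes 0.24 (list adjusted p = 0.0394), the gene symbols starting with RPS -0.46 (list adjusted p = 0.00554) and the serine carboxypeptidase-like (SCPL) genes -0.28 (list adjusted p = 0.0372), each with adjusted p = 0.716 with an estimated correlation. The calls of the heat shock, mitochondrial and SCPL lists were also lost with a signal minimum of 100, and that of the mitochondrial list with floors of 10 and 50 and without a floor. The median ratio of the mitochondrial list was 0.03 at 24 h and 0.55 at 48 h, at percentiles 72.1 and 99.8 of random lists. None of the 8 lists fixed in advance with at least 3 kept genes passed, the lowest adjusted p was 0.062, for early immune signalling, and 0 of their members passed over all genes, with 1 (DFR, -1.23 ± 0.37) when adjusted over the list alone. In limma 6 probe sets were higher and 0 lower, and 793 had an unadjusted p under 0.05. The call of AT1G26380 was lost when any 1 array other than a P. syringae array was left out, with adjusted p between 0.0564 and 0.673, and also with a floor of 50, without a filter, with a signal minimum of 100 and with quantile normalization. Without the A. brassicicola 48 h array, or with its 2 arrays and their own 2 control arrays alone, no probe set passed, and 3 were higher without a filter or with quantile normalization and 10 without a floor. At least 2-fold at both times, 72 were higher and 19 lower, against a simulated mean of 28.0 and 27.9, and 47 moved in opposite directions at the 2 times. The simulated mean leaves out differences between control arrays of different hours. The counts of 72 and 19 depended on the floor and on the reference. With a floor of 10 there were 112 higher and 33 lower, and with a floor of 50 there were 8 lower. With the pooled control 170 were higher and 96 lower, and against the 24 h control, a reference chosen after seeing the data, 223 and 131.

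P. rapae feeding went with higher values of anthocyanin synthesis genes, none of which passed one by one. DFR (AT5G42800) had 2.27 ± 0.38 (adjusted p = 0.16), UF3GT (AT5G54060) 2.16 ± 0.70 (adjusted p = 0.488) and UGT75C1 (AT4G14090) 1.74 ± 0.72, all enzymes of anthocyanin synthesis and all at least 2-fold higher at both times. As a list of 3 they passed (median 2.16, adjusted p = 0.000948, and adjusted p = 0.716 with an estimated correlation), with 0 members past the test over all genes and 3 when adjusted over the list alone. The signals at 12 and 24 h with P. rapae were 317.5 and 325.8 for DFR, 225.3 and 119.2 for UF3GT and 177.6 and 80 for UGT75C1. The unattacked 72 h control array had higher signals, 367.8, 264.8 and 249.9 in the same order. The F. occidentalis 24 h array had 264.8, 138.8 and 116.2. Such levels were thus not particular to P. rapae. None of the other lists fixed in advance with at least 3 kept genes passed, with 0 members past the test over all genes and, when adjusted over the list alone, 2 of 5 cell wall loosening genes (EXPA15, 0.74 ± 0.20, and EXPA8, -1.54 ± 0.46) and 1 of 4 salicylate signalling genes (GRX480). In smaller lists, JMT (1.18 ± 0.25) and BCAT4 (1.59 ± 0.50) also passed when adjusted over the list alone and not over all genes. AT4G17470 had signals of 2220.9 and 2284.1 against 29.3 and 422.9 (4.81 ± 0.88, adjusted p = 0.185), the jacalin-type lectin gene JAL23 (AT2G39330) 2.73 ± 0.36 and GRX480 2.57 ± 0.39 (adjusted p = 0.132). PDF1.2 had signals of 260.5 and 265.2, against 352.4 and 375.3 in the controls. Below the controls, AT2G05540 (-1.57), the plastid ribosomal protein genes rpl36 (-1.22) and rpl14 (-1.03), AT4G21870 (-1.16) and AT5G57760 (-1.07) led among probe sets with 1 listed gene, and none passed.

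Among the added lists, cytosolic ribosomal proteins had a median of -0.17 over 105 genes with P. rapae (adjusted p = 0.000131), core histones -0.58 over 6 (adjusted p = 0.0106; HTB11 -0.84, HTB1 -0.71) and the SWEET sugar transporters 0.53 over 7 (adjusted p = 0.0378; SWEET16 1.21, SWEET17 0.89), each with adjusted p = 0.716 with an estimated correlation and with no member past the test. The histone and SWEET calls were also lost with a signal minimum of 100, and the SWEET call with a floor of 50 and without a filter. The median ratio of the ribosomal list was -0.25 at 12 h and -0.06 at 24 h, at percentiles 0 and 38.5 of random lists. In limma 1 probe set was higher (256933_at without a listed gene, 3.15, adjusted p = 0.00812) and 0 lower, and 953 had an unadjusted p under 0.05. Without either P. rapae array, either P. syringae array or the 12 h control array no probe set was higher, without the 24 h control array 3 were, and with the P. rapae arrays and their own 2 control arrays alone 54 were higher and 10 lower, among them DFR, UF3GT, JAL23 and GRX480. The counts from the P. rapae arrays and their own control arrays alone rest on fewer residual degrees of freedom and are not comparable with the main fit. Without a filter 23 were higher, with time as 12 h against later hours 10, and with a floor of 50 there were 0. At least 2-fold at both times, 135 were higher and 31 lower, against a simulated mean of 28.6 and 28.1 and a simulated maximum of 41 and 49. These simulated numbers leave out differences between control arrays of different hours.

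F. occidentalis feeding went with higher signals of PDF1.2 and a glucanase gene at both times. PDF1.2 had signals of 2327.7 and 4267.3 against 375.3 and 34.7 (3.92 ± 1.24, adjusted p = 0.3), AT1G54020 3.02 ± 0.76, the glucanase gene AT4G16260 3.2 ± 0.56, GRX480 2.27 ± 0.38 and EXO (AT4G08950), a brassinosteroid-responsive gene, 3.41 ± 0.63, none of which passed. The thionin gene THI2.1 (AT1G72260) had 2.16 ± 0.42 (adjusted p = 0.13). Below the controls, AT1G62510 (-3.24 ± 0.45), the cytochrome P450 gene CYP71B26 (-2.69), AT5G35970 (-2.40), AT5G03230 (-1.72) and AT1G69160 (-1.44) led among probe sets with 1 listed gene, and none passed. The list of early immune signalling passed (median 1.01, adjusted p = 0.0272, and adjusted p = 0.716 with an estimated correlation), with 0 of 5 genes past the test over all genes and 3 when adjusted over the list alone, led by PUB23 (1.52 ± 0.39) and ZAT10 (1.32 ± 0.45). This call was also lost with a floor of 50 and with a signal minimum of 100. None of the other lists fixed in advance with at least 3 kept genes passed, with 0 members past the test over all genes and, when adjusted over the list alone, 1 of 3 flavonoid genes (DFR, 1.44 ± 0.37) and 1 of 4 salicylate signalling genes (GRX480). In smaller lists, THI2.1, PDF1.2, PDF1.2b (3.41 ± 1.24), OPCL1 (1.18 ± 0.32) and, with lower values, HCT (-0.66 ± 0.22) also passed when adjusted over the list alone and not over all genes. IGPS (0.87 ± 0.28), the only kept gene of its list, had an unadjusted p of 0.0141 in limma and did not pass over all genes (adjusted p = 0.309). The chitinase and glucanase genes had a median of 0.79 (adjusted p = 0.0133, and adjusted p = 0.716 with an estimated correlation), and that call was lost with a floor of 50.

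No probe set passed in limma for F. occidentalis, 1471 had an unadjusted p under 0.05, and the lowest adjusted p was 0.0538. Without the F. occidentalis 48 h array 7 were higher and 10 lower, without either P. syringae array 8 higher and 1 lower, and with time as 12 h against later hours 6 higher. At least 2-fold at both times, 176 were higher and 63 lower, against a simulated mean of 28.0 and 27.0 (360 and 229 with the pooled control), while 271 moved in opposite directions, and the ratios at the 2 times correlated across probe sets with r = -0.03. The simulated mean leaves out differences between control arrays of different hours. With the arrays taken as 12 and 24 h, a choice made after seeing the data, r was 0.43, 7 probe sets moved in opposite directions and 15 rather than 63 were lower, and limma called 2 higher.

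**Figure D3:**
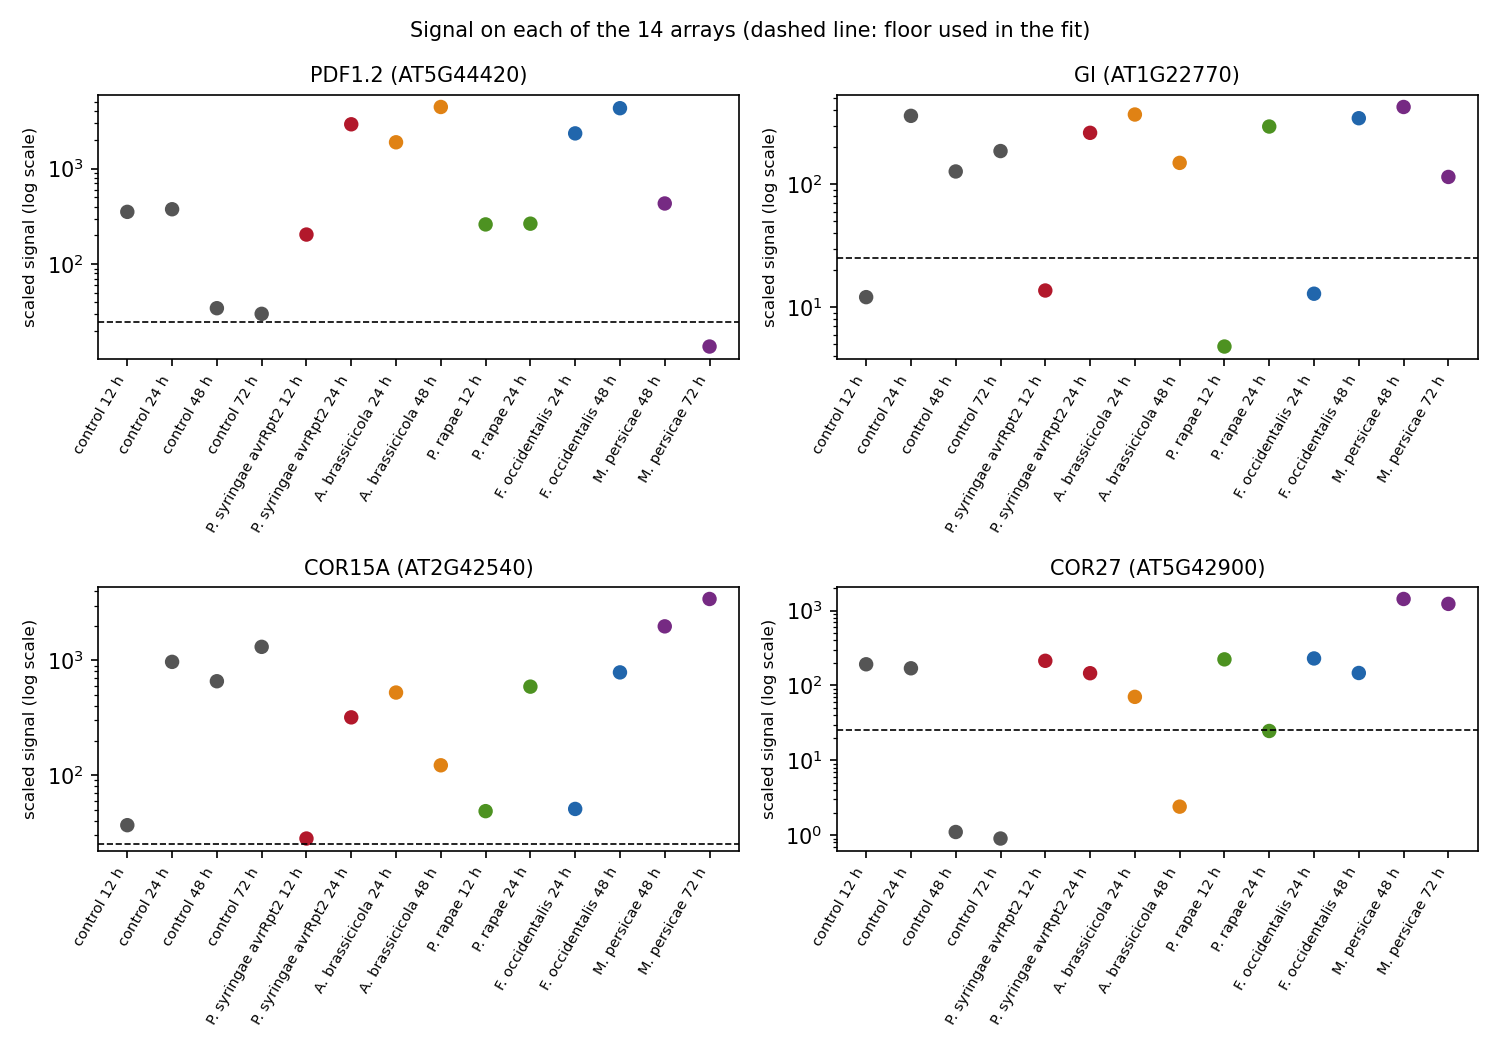
Scaled signal (log scale) of PDF1.2, GI, COR15A and COR27 on each of the 14 arrays (x axis), 1 point per array, coloured by attacker; the dashed line is the floor of 25. PDF1.2 is above 1000 on the A. brassicicola and F. occidentalis arrays and the P. syringae 24 h array, GI is under the floor on the 12 h arrays and the F. occidentalis 24 h array, and COR27 is under it on the 48 and 72 h controls, the A. brassicicola 48 h array and the P. rapae 24 h array.

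M. persicae feeding went with higher signals of COR27 and other evening and morning phased genes, all measured against control arrays of 48 and 72 h that themselves stood apart from the 24 h control and had log2 actin 3' to 5' ratios of 1.4 and 2.2, against 0.92 and 0.58 on the M. persicae arrays. The same ratios of ubiquitin (1.00 and 0.98 against 1.06 and 1.09) and GAPDH (-0.03 and -0.04 against -0.08 and -0.42) did not show this gap on both arrays. COR27 rose by log2 5.50 ± 0.61 (adjusted p = 0.00345), its relative AT4G33980 by 3.80 ± 0.37, EXO by 4.23 ± 0.64 and AKINBETA1 (AT5G21170), a subunit gene of the energy-sensing kinase SnRK1, by 3.88 ± 0.63. AT3G15630 (4.98), AT3G59350 (4.75), AT3G15450 (4.68), AT5G19120 (3.98), AT5G61590 (3.98), AT3G23550 (3.89), AT5G50450 (3.87) and AT1G72060 (3.49) complete the 12 largest increases among probe sets with 1 listed gene. The largest decreases among these probe sets were those of AT3G21670, a nitrate transporter family gene (-5.39 ± 0.83, adjusted p = 0.00816), CYP71B26 (-4.38 ± 0.45), AT5G12110 (-4.08), AT5G35970 (-4.02), AT3G28270 (-3.88), TBL26 (-3.82), AT1G13650 (-3.70) and AT3G48460 (-3.70). For 6 of the 12 increases at least 1 control signal, and for 5 of the 8 decreases at least 1 M. persicae signal, was under the floor. PDF1.2 had signals of 431.1 and 13.8, against 34.7 and 30.3. For COR27 the control signals were 1.1 and 0.9, and against the 24 h control its ratios were log2 3.08 and 2.86 in place of at least 5.84 and 5.62. For AT3G21670 they were -3.25 and -3.38, and for CYP71B26 -3.16 and -3.28. These genes are among those with the largest ratios left against the 24 h control. Of the 930 probe sets higher and 948 lower at both times, 141 and 139 stayed at least 2-fold the same way against it. AKINBETA1 had a signal of 447.6 on the 24 h control. Its signals were 1108.4 and 1137 with M. persicae and 76.7 and 36.3 on the 48 and 72 h controls.

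Of 6 kept evening and morning phased genes, 4 rose with M. persicae (COR27, AT4G33980, AT1G07050 by 3.33 ± 0.50 and CCL by 2.02 ± 0.51), with a list median of 2.76 (adjusted p = 0.0108). The M. persicae arrays lay at 0.65 (48 h) and 0.46 (72 h) between the 12 h control and the later controls. Whether their hour of harvest differed from that of their control arrays was not tested. Of 105 cytosolic ribosomal protein genes, 18 fell and 0 rose, with a median of -0.36 (adjusted p = 3.66e-08). Of 8 heat shock protein genes 1 fell (AT5G48570, -2.96 ± 0.54), with a median of -1.12 (adjusted p = 0.0372). The median ratio of these 8 genes was -0.32 at 48 h and -2.33 at 72 h, at percentiles 7.1 and 0 of random lists. The ATG genes of autophagy had 3 of 8 members higher and a median of 0.56 (adjusted p = 0.0331), and the gene symbols starting with GH 3 of 5 lower (GH9C2 -2.75 and GH9B8 -2.29 among them) and a median of -0.99 (adjusted p = 0.0485). Each of these 5 lists had adjusted p = 0.716 with an estimated correlation, and the heat shock, ATG and GH calls were also lost with a signal minimum of 100, the heat shock call with a floor of 50 and the GH call with quantile normalization. The glucosinolate synthesis genes UGT74B1 (-1.96 ± 0.33, adjusted p = 0.0104) and UGT74C1 (-2.25 ± 0.43, adjusted p = 0.0148) fell, as did HCT of lignin synthesis (-1.13 ± 0.22, adjusted p = 0.0158). BCAT4 (-1.33 ± 0.50) and JMT (-0.77 ± 0.25) passed only when adjusted over the list alone. IGPS (-0.67 ± 0.29), the only kept gene of its list, had an unadjusted p of 0.0472 in limma and did not pass over all genes (adjusted p = 0.139). Of the 8 lists fixed in advance with at least 3 kept genes none passed: 1 of 5 early immune signalling genes rose (1 when adjusted over the list alone; PUB24, 1.47 ± 0.38), 1 of 5 cell wall loosening genes rose (EXPA16, 1.97 ± 0.32; when adjusted over the list alone 3 passed, EXPA16 and XTH16 with higher and EXPA15 with lower values), 1 of 3 endoplasmic reticulum folding genes fell (1 when adjusted over the list alone; CRT1B, -0.91 ± 0.20), and 0 of 4 abscisic acid, drought and cold genes passed (2 when adjusted over the list alone; list median 1.59, adjusted p = 0.261).

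In limma 1074 probe sets were higher and 996 lower with M. persicae, 4274 had an unadjusted p under 0.05, and 930 were higher and 948 lower at least 2-fold at both times, against a simulated mean of 28.0 and 28.3. This mean leaves out differences between control arrays of different hours, where 617 were higher and 624 lower against the 24 h control. The control and M. persicae arrays are the only ones of 72 h, so without either of them that time point drops out by design, and the 48 h arrays alone gave 3 higher and 1 lower, with none of the 20 named genes past the test. Without the 48 h control array 142 were higher and 162 lower, without the M. persicae 48 h array 330 and 424, and without the 12 h control array 654 and 639. With time as 12 h against later hours 628 were higher and 586 lower, with the M. persicae arrays and their own 2 control arrays alone 1621 were higher, and with the F. occidentalis arrays taken as 12 and 24 h 1757 were higher and 1573 lower. Without the 48 and 72 h control arrays 0 were higher and 0 lower, a fit in which the M. persicae 72 h array is alone at its hour, and 1 and 0 with time as 12 h against later hours as well. Against the 24 h control array for both hours, 186 were at least 2-fold higher and 255 lower. The shifted hours, the fits without these control arrays and the 24 h reference were chosen after seeing the data.

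**Figure D4:**
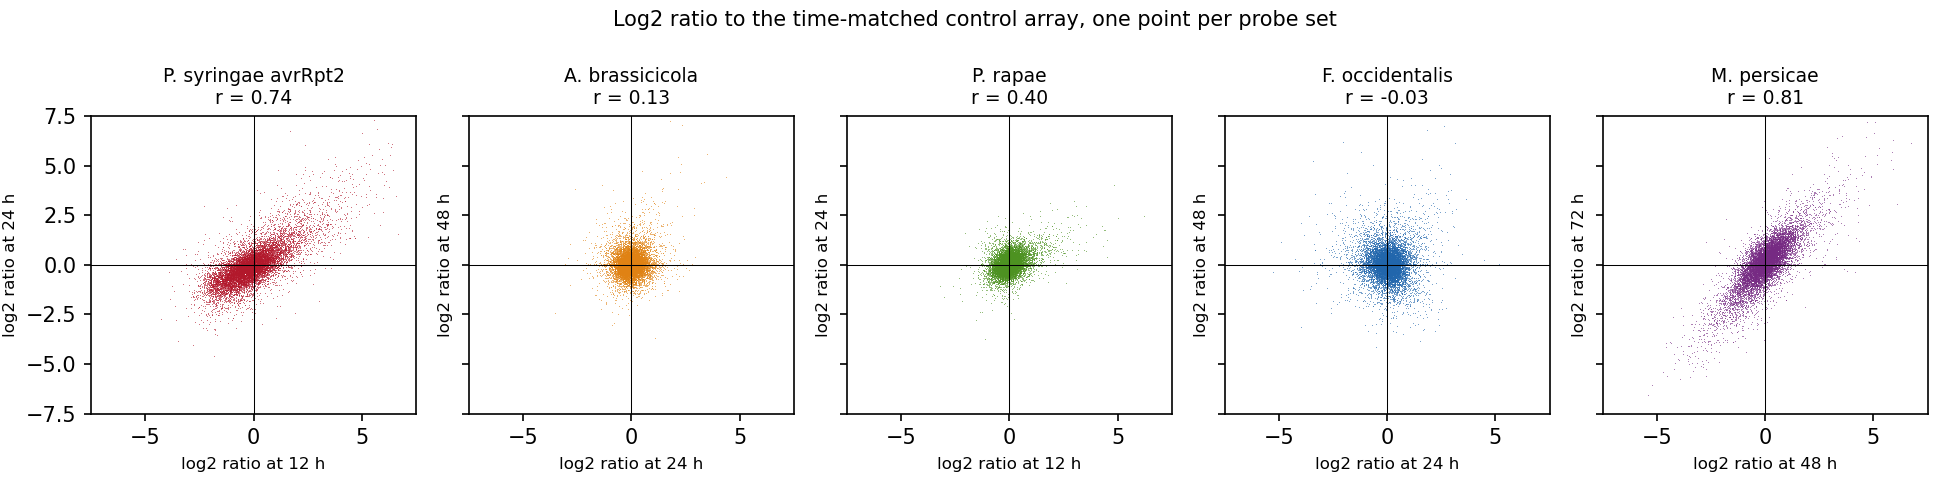
Log2 ratio to the control array of the same hour at the earlier (x axis) and later (y axis) time point of each attacker, 1 point per probe set kept. The correlation across probe sets is 0.74 for P. syringae, 0.81 for M. persicae, 0.40 for P. rapae, 0.13 for A. brassicicola and -0.03 for F. occidentalis; probe sets are not independent replicates.

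The jasmonate oxygenase genes AT2G38240 and JRG21 were among those that differed most between P. syringae on Col-0 (12 and 24 h) and A. brassicicola on pad3-1 (24 and 48 h). Pathogen and genotype cannot be separated in this contrast, and the hours differ in part. Log2 changes with P. syringae exceeded those with A. brassicicola by 5.89 ± 0.78 for AT2G38240 (adjusted p = 0.00366), 5.20 ± 0.79 for AT4G12490, 5.02 ± 0.85 for JRG21, 4.99 ± 0.43 for AT4G22470 and 4.64 ± 0.50 for AT3G18250. The difference was -3.47 ± 0.54 for EXPA8 (adjusted p = 0.00676), -3.07 ± 0.43 for AT2G04790, -2.88 ± 0.78 for AT1G78995, -2.64 ± 0.25 for AT2G29290 and -2.58 ± 0.72 for AT5G44020. In limma 1739 probe sets differed, 851 with higher and 888 with lower values for P. syringae. Without the A. brassicicola 24 h array 82 differed and 7 of these 10 genes no longer passed, AT2G38240, AT4G12490, JRG21 and EXPA8 among them, and without the 12 h control array, the P. syringae 12 or 24 h array or the A. brassicicola 48 h array 773, 817, 1022 and 866 differed. With the F. occidentalis arrays taken as 12 and 24 h 2695 differed. P. rapae and F. occidentalis, a chewing and a cell-feeding insect, gave 0 differing probe sets in limma (845 with an unadjusted p under 0.05, lowest adjusted p 0.419), 11 without the F. occidentalis 48 h array and 2 without a filter. M. persicae and F. occidentalis also gave 0 (2090 with an unadjusted p under 0.05, lowest adjusted p 0.0734), but 629 without the F. occidentalis 48 h array and 1057 with the F. occidentalis arrays taken as 12 and 24 h. With time as 12 h against later hours 29 differed (87 without the 48 and 72 h control arrays as well), without a filter 28, with a floor of 50 there were 12 and with a floor of 10 there were 3.

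The probe set 256933_at, without a listed gene, was the only 1 called higher in 4 attackers, with log2 changes of 6.29 for P. syringae, 3.83 for A. brassicicola, 3.15 for P. rapae and 1.17 for M. persicae, and 1.38 (adjusted p = 0.116) for F. occidentalis. The chitinase gene AT2G43570 and AT1G25400 were the named genes among 12 probe sets at least 2-fold higher at both times in 4 attackers, and none was so in all 5. Of the probe sets at least 2-fold higher at both times, P. syringae and F. occidentalis shared 109 (14.1 for independent lists, 1.7 simulated with shared controls and no effect), P. syringae and P. rapae 61 (10.8 and 4.4), P. syringae and A. brassicicola 53 (5.8 and 1.7), P. rapae and F. occidentalis 45 (1.9 and 1.7), A. brassicicola and F. occidentalis 25 (1.0 and 3.9) and F. occidentalis and M. persicae 51 (13.3 and 1.7). P. syringae and M. persicae, which share no control array, had 115 higher in both (74.6 and 0.8), 96 lower in both (68.5 and 0.8) and 167 in opposite directions. P. rapae and M. persicae, which also share no control array, had 5 higher in both (10.2 and 0.7) and 45 in opposite directions, with a covariance of -0.03 against a simulated 0. A. brassicicola shared 5 higher with P. rapae (0.8 and 1.7) and 12 with M. persicae (5.4 and 1.7). The covariance of the log2 changes was 0.207 for P. syringae and F. occidentalis against a simulated 0.031, 0.27 for F. occidentalis and M. persicae against 0.031, and 0.065 for A. brassicicola and F. occidentalis against 0.062. Part of each excess between attackers that share control arrays may come from those arrays.

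Markers of other cell types gave no call over all genes. The root marker PYK10 had log2 changes of 1.07 for P. syringae (adjusted p = 0.0636), 0.98 for A. brassicicola, 0.91 for P. rapae, 1.07 for F. occidentalis and 0.12 for M. persicae. It is the only kept gene of its list, so no adjustment over the list applies. Its unadjusted p in limma was under 0.05 with 4 attackers (0.0211 for P. syringae, 0.0281 for A. brassicicola, 0.0422 for P. rapae and 0.0186 for F. occidentalis). The guard cell marker GC1 lay between -0.84 and -0.17 and FAMA between -0.52 and 0.46. PR1, VSP2, LOX2 and PAD3 have no probe set listed for them here and were not analysed.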

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

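The 3 tests of the hour of the F. occidentalis 24 h array were chosen after its values were seen, and the bound of the test of an exchange was changed once after its value was known; the tests of the control arrays behind the M. persicae values were set before their results were seen, but the rule for reading the test of an aphid response was changed after its value was known, when by its first bound a response would have been excluded.

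With F. occidentalis, gene lists lay in opposite directions at the 2 time points, and this difference between time points was not tested. The 4 genes of abscisic acid, drought and cold response had a median log2 ratio of -2.88 at 24 h and 1.56 at 48 h, at percentiles 0 and 99.9 of random lists. The 3 genes of auxin response had -3.27 at 24 h and 1.99 at 48 h, also at percentiles 0 and 99.9. The 6 evening and morning phased genes lay the same way, with -0.67 at 24 h and 1.54 at 48 h, at percentiles 0.5 and 100. The cold and auxin lists were picked from the 200 pairs of list and attacker for opposite medians with extreme percentiles at both times. Their percentiles are therefore no test. The random lists also leave out the correlation between members, estimated at 0.849 for the cold list and 0.755 for the auxin list.

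The low values at 24 h went with the day phase of the F. occidentalis 24 h array. Its median position of 0.16 was the value that a harvest about as early as that of the other 12 h arrays would give, so an earlier harvest than labelled may be the source. The high values at 48 h depended on the 48 h control array. All genes of the cold and auxin lists had lower signals on it than on the 24 h control, such as COR15B (67.9 against 654.8), IAA29 (62.7 against 394.1) and COR15A (657.2 against 969.3). The P. syringae and P. rapae 12 h arrays lay at 0.27 and 0.13, on the side of the 12 h control. This argues against an exchange of the F. occidentalis 24 h array with either of them. An exchange with the 12 h control array could not be tested, because that array defines 0 on this scale. A response of clock-driven genes to thrips stays open, because no array separates feeding from the hour of harvest at 24 h. The later array lay at 0.93, which cannot tell 24 h from 48 h. Over all probe sets kept, its log2 signal correlated at 0.96 with the 24 h control and 0.866 with the 48 h control. The F. occidentalis 24 h array had 0.94 with the 12 h control and 0.903 with the 24 h control. These values cannot decide, since the M. persicae 48 h array also lay nearer the 24 h control (0.927) than the 48 h control (0.805).

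The M. persicae values depended on the 48 and 72 h control arrays. Of the probe sets at least 2-fold at both times against these arrays, 14.9 percent stayed so against the 24 h control, so the state of these control arrays may be the main source of the values. A response to aphids was neither shown nor excluded: 441 probe sets were at least 2-fold the same way on both M. persicae arrays against the 24 h control, fewer than the 1241 on the 48 and 72 h control arrays, but this comparison cannot decide, because against the 24 h control the hour and the feeding are confounded, and a response that opposed a real change over time would lower the 441 and the 14.9 percent alike. Whether the 48 h control array alone was out of place could not be decided, since over the probe sets higher with M. persicae the A. brassicicola 48 h array had a median log2 ratio of 0.48, the F. occidentalis 48 h array 1.05 and the M. persicae 48 h array 1.57. The F. occidentalis value counts here only if its labelled hour holds, and the 24 h control had 1.01 over these probe sets. No biological difference between the control plants is named in the labels, and none was tested.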

How the results depend on the processing

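The fits with the F. occidentalis arrays taken as 12 and 24 h or left out, the 24 h control array as reference and the fits without the 48 and 72 h control arrays were chosen after the result was seen. No paired analysis was possible because each group holds 1 array, so far as pairing by replicate number goes; arrays were matched by hour, by the time term and in the fits on the attacker's 2 arrays and 2 control arrays. No called result reversed. Among counts, 213 stayed within 1.5 times and 59 did not under other settings, and 128 and 54 when an array was left out. For named genes, 1231 values of called genes stayed past the threshold and 176 did not, and 15 of genes not called passed. For gene lists, 94 stayed past it and 39 did not, 19 of these by the estimated correlation, 20 of lists not called passed, and 51 of lists not called changed sign without passing. Signals near the floor of 25 limit the ratios of weak probe sets. Except where fewer arrays or fewer genes entered, the cause was not tested.

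In limma, floor of 10 gave P. rapae 1 lower and M. persicae against F. occidentalis 3. Floor of 50 gave P. rapae 0 higher and M. persicae against F. occidentalis 12. No floor, log2 of the signal plus 16, gave A. brassicicola 10 higher and P. rapae 1 lower. No filter gave A. brassicicola 3 higher, P. rapae 23 higher, P. rapae against F. occidentalis 2 and M. persicae against F. occidentalis 28. Quantile normalization gave A. brassicicola 3 higher. Time as 12 h against later hours gave P. rapae 10 higher, F. occidentalis 6 higher, M. persicae 628 higher and 586 lower, and M. persicae against F. occidentalis 29. Only the attacker's 2 arrays and 2 control arrays gave P. syringae 1095 lower, A. brassicicola 0 higher, P. rapae 54 higher and 10 lower, and M. persicae 1621 higher. The F. occidentalis arrays taken as 12 and 24 h gave P. rapae 2 higher, F. occidentalis 2 higher, M. persicae 1757 higher and 1573 lower, P. syringae against A. brassicicola 2695 and M. persicae against F. occidentalis 1057. Without the F. occidentalis arrays P. rapae had 2 higher. Without the control 48 h and 72 h arrays A. brassicicola had 1 higher, P. rapae 2 higher and M. persicae 0 higher and 0 lower. With time as 12 h against later hours as well, A. brassicicola had 1 lower, P. rapae 0 higher, M. persicae 1 higher and 0 lower, and M. persicae against F. occidentalis 87.

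At least 2-fold at both times, floor of 10 gave A. brassicicola 112 higher and 33 lower, and floor of 50 gave 8 lower. The pooled control gave A. brassicicola 170 higher and 96 lower, and F. occidentalis 360 higher and 229 lower. The 24 h control array gave A. brassicicola 223 higher and 131 lower, and M. persicae 186 higher and 255 lower. The F. occidentalis arrays taken as 12 and 24 h gave 15 lower for that insect. At 3-fold, higher and lower were 515 and 175 for P. syringae, 20 and 1 for A. brassicicola, 38 and 2 for P. rapae, 65 and 13 for F. occidentalis and 378 and 409 for M. persicae.

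Leaving out each array in turn gave, in limma, 784 to 1663 higher and 612 to 2347 lower for P. syringae, 0 to 10 higher for A. brassicicola, 0 to 3 higher for P. rapae, 0 to 8 higher and 0 to 10 lower for F. occidentalis, and 3 to 1444 higher and 1 to 1356 lower for M. persicae. Between attackers it gave 82 to 2066 for P. syringae against A. brassicicola, 0 to 11 for P. rapae against F. occidentalis and 0 to 629 for M. persicae against F. occidentalis. P. syringae was lowest without the 12 h control array, A. brassicicola without its 48 h array and M. persicae without the 72 h control or its own 72 h array, where the 72 h time point drops out by design, as it does without the control 48 h and 72 h arrays. A minimum of 100, variances without a trend and the Col-0 arrays alone left every count within 1.5 times. The named genes lost their call in 0 of 51 with floor of 10, 4 with floor of 50, 6 without a filter, 2 with quantile normalization, 10 with time as 12 h against later hours and 21 without the control 48 h and 72 h arrays.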

Other observations

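The gene families, the genes kept against the 24 h control and the genes of F. occidentalis at other hours were singled out after their values were seen.

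With P. syringae, the glucosyltransferase genes UGT76E12 (log2 4.4 ± 0.32), UGT76B1 (4.26 ± 0.21), whose product glucosylates isoleucic and salicylic acid, UGT87A2 (3.11 ± 0.36) and UGT73D1 (2.22 ± 0.42) rose, and of 23 kept UGT genes 4 rose and 5 fell, UGT74D1 (-1.31 ± 0.39) and UGT88A1 (-1.20 ± 0.23) among them, while over all probe sets 3652 of 12344 passed. The glucosidase genes BGLU46 (4.34 ± 0.37), BGLU45 (3.3 ± 0.38), both linked to monolignol glucosides, BGLU27 (3.29 ± 0.32) and BGLU16 (1.56 ± 0.44) rose and BGLU40 (-0.99 ± 0.27) fell. Neither family passed as a list (adjusted p = 0.596 for UGT and 0.232 for BGLU).

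With M. persicae, the sugar transporter genes SWEET11 (1.68 ± 0.26) and SWEET4 (1.37 ± 0.37) rose and SWEET17 (-1.54 ± 0.26) and SWEET13 (-1.24 ± 0.36) fell, while SWEET1 (-0.21), SWEET2 (-2.01) and SWEET16 (-0.11) did not pass, and the list of 7 did not pass (adjusted p = 0.657). The autophagy genes ATG8E (3.26 ± 0.64), ATG8D (1.51) and ATG8F (1.00) rose, and UGT78D1 (-2.83 ± 0.44), UGT74D1 (-2.52 ± 0.39) and the chitinase-like gene AT3G47540 (-1.96 ± 0.45) fell. Of 23 kept UGT genes 3 rose and 5 fell (list adjusted p = 0.159). Of 8 chitinase and glucanase genes 0 rose and 1 fell (list adjusted p = 0.782), while 2 were at least 2-fold higher at both times. These values used the 48 and 72 h control arrays. Against the 24 h control, the log2 ratios at 48 and 72 h were 2.70 and 3.00 for AT1G72060, 2.72 and 2.12 for AT4G33980, 1.88 and 2.17 for AT3G59350, 1.71 and 2.59 for AT3G60420, -2.39 and -2.42 for AT1G19450 and -2.19 and -2.71 for AT5G48900.

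With the F. occidentalis arrays set against the 12 and 24 h controls, the log2 ratios were 2.93 and 3.72 for AT1G54020, 2.72 and 3.51 for PDF1.2, 3.12 and 2.64 for AT4G16260, 2.71 and 2.33 for JAL23, 2.27 and 2.59 for THI2.1 and 2.42 and 2.13 for GRX480. Of the genes with values below these controls, the ratios were -2.67 and -1.30 for psbA, -2.20 and -1.26 for atpH and -1.98 and -1.60 for rpl16. None of these genes passed in that fit, in which 2 probe sets were higher. Of the 176 probe sets at least 2-fold higher at the labelled hours, 94 were also higher at these hours, and of the 63 lower, 3 were.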
